A study of Mus musculus with 2 samples.

How the data were processed

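The series compared trimethylation of lysine 4 of histone H3 (H3K4me3), a mark of active and poised promoters, between a wild-type mouse embryonic fibroblast line (WT) and a line lacking Lsh (Lsh_KO). Lsh, also called Hells, is a chromatin remodeller of the SNF2 family that is needed for normal DNA methylation. Each group had 1 library. Per the labels' protocols, 20000000 cells per line were digested with micrococcal nuclease to mostly single nucleosomes, precipitated with an antibody against H3K4me3, amplified for 20 cycles and cut from a gel at 200 to 400 bp. No input or control library was used here.

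For each library the authors deposited a list of aligned reads and a list of read counts in 200 bp windows, on build mm8 per the submitters' processing notes. In the deposited read lists, the position of each 25-base read is given with its strand, its bases, a match code and an alignment score. The deposited alignment score ran from 4 to 53 in both libraries. The aligner is not given in the sources used here. In the deposited window lists, whole-number counts of reads were given for every 200 bp window with at least 1 read, although the lists carry the name of peaks. The authors' rule for making these counts is not given in the sources used here. It was tested on the lists: when the reads were taken once per position and strand and moved 100 bp from their leftmost base, 0 windows of the deposited lists fell below the counts made from the read lists. The window lists held a further 1598335 reads for WT and 1759904 for Lsh_KO, of an origin that the sources used here do not give. These further reads were used as a technical repeat of each library. No normalisation of either kind of deposited count was found.

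From the deposited positions, 1 read was kept per position and strand and moved 75 bp in its reading direction. The plan made before the data were examined was to count reads around transcription start sites. No genome or gene annotation of mm8 was used here, so the plan's own fallback was followed: reads were counted in fixed windows of 2 kb, and no gene was named from a position. The gene lists fixed in advance, the promoter of the targeted gene, the distance of regions to start sites, and the profile around start sites were therefore not analysed here. The table of gene names used here is on assembly GRCm38.p6, and only the chromosome of Hells was taken from it.

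A window was called marked in a library with at least 10 reads and at least 5 times the mean background, which was taken over windows with fewer than 10 reads in both libraries. The ratio of Lsh_KO to WT was scaled so that the median ratio of the windows marked in both was 1. A window was called higher or lower when the ratio was at least 2-fold, its exact conditional (Clopper-Pearson) 95% interval excluded 1, and the libraries held at least 20 reads together. These intervals and all others cover counting error only, and amplified reads without molecular identifiers are not independent molecules. A window was called gained or lost when it was marked in 1 library and below 2 times background in the other. A ratio against 0 reads was computed against a floor of 3 reads.

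Some rules were set only after the data were examined, because the deposited lists held no peaks. Regions were built from the deposited windows with at least 6 reads, joined across gaps of up to 1 kb and kept with at least 20 reads. Called windows of 1 direction were joined into loci across up to 10 kb. The loci named are the 15 higher and the 15 lower whose interval bound nearest to 1 lies farthest from 1, and the 5 leading gained and 5 leading lost windows, which is the planned rule for genes applied to loci. Base composition came from the reads inside each region, and a region was called CpG-rich when its GC content was over 50% and its observed over expected CpG over 0.6. The ratio of background reads along chromosomes was taken from background windows in bins of 5 Mb. It is an indirect reading of copy number, which was not measured. Repeat-like reads were those outside marked windows that held a 16-base word seen at least 50 times in the libraries thinned to equal numbers.

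The calling rule was tested on simulated counts for the 1285045 covered windows, with 200 windows changed per fold size and direction. The changed windows were drawn from those marked in both libraries, so recovery in windows marked in 1 library was not simulated. The rule recovered 57.0% of 2-fold higher and 42.0% of 2-fold lower windows, 98.5% and 76.5% at 3-fold, and 100% and 81.5% at 4-fold. A 2-fold change lies at the threshold of the rule, so many such windows fall below it at any depth. In 20 simulations with no change and the same ratio in every window, counting error alone gave a mean of 192 higher and 142 lower windows. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives covered the scaling, repeated reads, window size, read shift, minimum of reads, fold, depth, background subtraction, marking threshold and region overlap.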

Results

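H3K4me3 was profiled in a WT and an Lsh_KO mouse embryonic fibroblast line, with 1 library each. No replicates were available, so no test of the genotype was possible: each comparison below describes these 2 libraries, and a difference between the cell lines that is unrelated to Lsh was not separated from one due to its loss. The WT library held 2869399 aligned reads, of which 13.9% repeated a position and strand, leaving 2471782 distinct reads. The Lsh_KO library held 3428628 reads, of which 18.6% were repeats, leaving 2790389. The libraries were sequenced in lanes 2 and 3 of the same run, and 84.5% of WT and 84.8% of Lsh_KO reads matched the reference without a mismatch.

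The first question was how much of the genome carried the mark and whether its level differed between the lines. Of 1285045 windows of 2 kb, 22255 were marked in WT and 24045 in Lsh_KO, and 18150 of these were marked in both. Windows marked in either library took 30.8% of WT reads (95% Clopper-Pearson interval 30.7 to 30.8) and 38.6% of Lsh_KO reads (38.6 to 38.7). The background stood at 1.36 reads per window in both libraries. Scaled by total reads, the median window marked in both was 1.26-fold higher in Lsh_KO, a shift of 0.33 on the log2 scale. Without a control library or a spike-in, this shift was not separated from a more efficient precipitation. Ratios of windows, loci and regions below are relative to it unless stated otherwise.

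Most marked windows had similar levels in the 2 lines. Across windows marked in both, Pearson's r of log2 read counts was 0.868, and the central 90% of log2 ratios ran from -0.90 to 0.73. Of 21163 windows with enough reads, 730 were called higher and 1228 lower in Lsh_KO, 9.25% together. Counting error alone gave at most 212 higher and 156 lower windows in simulations. These gave every window the median ratio of the marked windows, so they do not measure the calls expected where the usual ratio was lower. The balance between directions depended on the scaling: 37.3% of called windows were higher with the median ratio, and 71.6% when scaled by total reads, with 1837 higher and 730 lower. The lower calls gathered among windows with few reads. Windows with 20 to 25 reads had a median log2 ratio of -0.37 and gave 90 higher and 342 lower calls, whereas those with 60 to 100 reads had a median of 0.06 and gave 141 higher and 124 lower.

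The called windows were compared with the further reads found only in the deposited window lists. At least 20 such reads were found in 551 of the 730 higher and 617 of the 1228 lower windows, and the rest were not compared. Of the 551 higher windows, 96.4% had the same direction, 55.0% were again at least 2-fold higher and 46.8% passed the calling rule again. Of the 617 lower windows, 98.2% had the same direction, 74.6% were again at least 2-fold lower and 68.6% passed the calling rule again. In neither direction was a compared window called the other way. Across 14751 windows marked in both lines by both kinds of reads, Pearson's r of the log2 ratios was 0.654. These reads carry the same sample labels and do not measure the spread between cultures.

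Some of the lower windows in Lsh_KO lay in clusters of neighbouring windows. The 1228 lower windows formed 1026 loci, of which 6 held at least 5 windows, and 1 of the 671 higher loci did. Folds of a cluster are given over its called windows, which were picked for being lower, and then over every window of the stretch. At chromosome 8, 60204001 to 60228000 (mm8), 10 called windows held 681 WT and 134 Lsh_KO reads, 7.22-fold lower in Lsh_KO (interval 5.99 to 8.76). All 12 windows of that stretch held 700 and 141 reads, 7.05-fold lower (5.88 to 8.52). On chromosome 11, 11 called windows between 96086001 and 96138000 held 469 and 55 reads, 12.1-fold lower (9.15 to 16.3), and all 26 windows held 595 and 154 reads, 5.49-fold lower (4.59 to 6.60). The uncalled window starting at 96134001 held 58 and 50 reads. A neighbouring locus at 96066001 to 96072000 held 90 and 14 reads, 9.14-fold lower (5.17 to 17.4). Chromosome 14, 62192001 to 62204000, held 253 and 42 reads in 5 windows, 8.56-fold lower (6.16 to 12.2), and over all 6 windows 412 and 222 reads, 2.64-fold lower (2.23 to 3.12). Chromosome 6, 52092001 to 52110000, held 305 and 79 reads in 6 windows, 5.49-fold lower (4.27 to 7.12), and over all 9 windows 410 and 217 reads, 2.68-fold lower (2.27 to 3.18). The other 2 clusters, named after their values were seen, differed less over their called windows. Chromosome 10, 79136001 to 79146000, held 115 and 56 reads, 2.92-fold lower (2.10 to 4.09). Chromosome 2, 104922001 to 104936000, held 322 and 166 reads in 5 called windows, 2.76-fold lower, and 619 and 487 over all 7 windows, 1.81-fold lower (1.60 to 2.04). Gene names were not assigned to any of these positions.

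**Figure D1:**
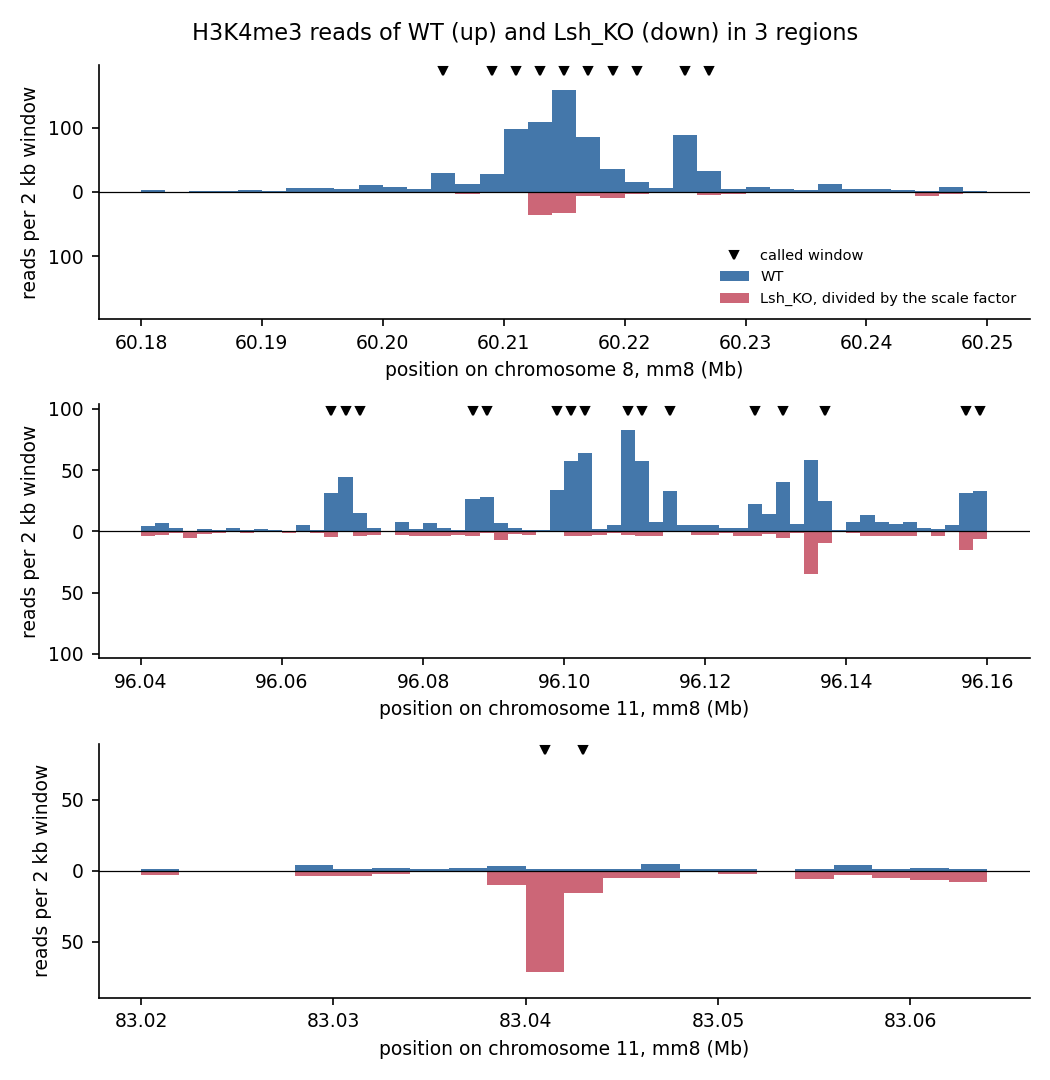
Distinct H3K4me3 reads per 2 kb window of WT (upward bars) and Lsh_KO (downward bars, divided by the scale factor of 1.42) on chromosomes 8 and 11, with triangles above called windows. The clusters starting at 60204001 and 96086001 hold 681 and 469 WT reads in their called windows against 134 and 55 Lsh_KO reads, and the locus from 83040001 to 83044000 holds 2 WT and 124 Lsh_KO reads.

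Other leading lower loci held fewer called windows than these clusters. Chromosome 9, 24520001 to 24526000, held 218 WT and 19 Lsh_KO reads, 16.3-fold lower (10.2 to 27.6), and chromosome X, 48856001 to 48860000, held 76 and 8 reads, 13.5-fold lower (6.52 to 32.4). Single windows starting at 8904001 on chromosome 19, at 23486001 on chromosome 10 and at 33000001 on chromosome 2 had 0 Lsh_KO reads against 27, 24 and 20 in WT. They were at least 12.8-fold, 11.4-fold and 9.47-fold lower, computed against a floor of 3 reads per window that leaves out the counting error of the WT reads. The exact 95% lower limits, which include it, were 9.71-fold, 8.55-fold and 7.02-fold. The remaining 5 of the 15 leading lower loci were on chromosomes 17 (starting at 69060001 and 14016001), 1 (38570001), 5 (21246001) and 2 (169324001), with 28 to 54 WT reads and 1 to 3 Lsh_KO reads.

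Higher loci were mostly isolated windows, 618 of 671 being single, and so were lower loci, 881 of 1026. Chromosome 11, 83040001 to 83044000, held 2 WT and 124 Lsh_KO reads, 43.6-fold higher (interval 11.8 to 364). Chromosome 17, 37602001 to 37606000, held 2 and 95 reads, 33.4-fold higher (9.0 to 280.0). The window starting at 77728001 on chromosome 8 held 1 and 86 reads, 60.5-fold higher (10.6 to 2418). Windows starting at 48704001 on chromosome 3 and at 6644001 on chromosome 19 held 0 WT reads against 55 and 44, at least 12.9-fold and 10.3-fold higher against the floor of 3 reads, with exact lower limits of 10.1-fold and 8.05-fold. Windows starting at 81936001 on chromosome 12 and at 21404001 on chromosome X each held 0 against 31 reads, at least 7.27-fold higher against the floor, with a lower limit of 5.57-fold. Chromosome 18, 86528001 to 86532000, held 20 and 241 reads, 8.48-fold higher (5.37 to 14.1), on a chromosome that had more Lsh_KO reads throughout. With the 5 Mb background ratio in the scaling, its log2 ratio of 3.08 was 2.38. Chromosome 11, 99958001 to 99962000, held 23 and 209 reads, 6.39-fold higher (4.15 to 10.3).

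A further 5 of the leading higher loci started at 88424001 and 96882001 on chromosome 15, 70036001 on chromosome 11, 71826001 on chromosome 5 and 170364001 on chromosome 2. They held 1 to 3 WT reads and 43 to 84 Lsh_KO reads. The window at 3092001 to 3094000 on chromosome 11 held 64 WT and 620 Lsh_KO distinct reads, 6.82-fold higher (5.26 to 8.96). With repeats of a position kept it held 79 and 3085 reads, and its log2 ratio of 2.77 was 4.70. There 37.6% of reads carried a mismatch, so reads from near-identical copies elsewhere are not excluded.

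Presence and absence of the mark were judged against the background of each library, without the scaling by the median ratio. In Lsh_KO, 959 windows were gained and 688 lost, of which 82 and 49 also passed the calling rule. The balance was opposite to that of the called windows, 730 higher and 1228 lower. In the further reads of the window lists, 544 of the gained windows were again under 2 times background in WT and 387 of the lost windows in Lsh_KO. The direction was the same in 76.5% and 91.6%, here with Lsh_KO divided by 1.43, the median ratio of the further reads. That division lowers the share for gained and raises it for lost windows, so these 2 shares are not comparable with each other. The leading gained windows were on chromosome 11 (83040001), 17 (37604001), 8 (77728001), 3 (48704001) and 19 (6644001), with 0 or 1 WT reads. The leading lost windows were 3 on chromosome 8 (60210001, 60224001 and 60204001), 1 on chromosome 9 (24520001) and 1 on chromosome 11 (96114001), with 0 to 2 Lsh_KO reads. Thinning the deeper library left 595 gained windows, against 864 lost, which turned the order of these counts.

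The extent of marked regions was then compared from the deposited windows. WT had 11184 regions covering 16.1 Mb and Lsh_KO had 11580 covering 18.7 Mb. The median width was 1200 bp in WT and 1400 bp in Lsh_KO. Regions were drawn with a fixed minimum of 6 reads per 200 bp and held 28.1% of window reads in WT and 38.3% in Lsh_KO, so width was not separated from this difference in share. Of the WT regions, 94.7% (94.3 to 95.1) overlapped an Lsh_KO region by at least 1 bp, and 91.2% (90.7 to 91.7) of Lsh_KO regions overlapped a WT region. Regions without a partner were weak, with a median of 30 reads against 91 in WT and 34 against 140 in Lsh_KO. In the union, 317 of 11820 regions with enough reads were higher and 514 lower, and scaling by total reads gave 887 and 290. Among 113 regions wider than 5 kb, 1 was higher and 10 were lower, and scaling by total reads gave 4 and 5. The higher one, named after its values were seen, spans 3081201 to 3096600 on chromosome 11 and contains the window at 3092001. There 34.2% of reads carried a mismatch, so reads from copies elsewhere are not excluded there either. The same share, 34.2%, was found in 1 of the 10 lower ones, from 39450801 to 39456800 on chromosome 17.

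Because Lsh is known for its role in DNA methylation, regions were grouped by CpG content. CpG-rich regions were called less often: of 7826, 1.33% were higher (95% interval 1.09 to 1.61) and 3.26% lower (2.88 to 3.68). Of 3994 CpG-poor regions, 5.33% were higher (4.66 to 6.08) and 6.48% lower (5.74 to 7.29). Scaled by total reads, the balance turned in both classes, with 5.18% higher and 1.67% lower among CpG-rich and 12.1% higher and 3.98% lower among CpG-poor regions. In the 456 regions with an observed over expected CpG under 0.3, 10.96% were higher (8.25 to 14.2) and 19.3% lower (15.8 to 23.2). These regions also had fewer reads, with a median of 20 in WT and 25 in Lsh_KO against 49 and 73 in CpG-rich regions. Their median log2 ratio was -0.17, with quartiles of -0.82 and 0.44. Of these 456 regions, 100 were drawn only in WT and 133 only in Lsh_KO, and so entered partly because of a difference. The scaling centres the ratios on the bulk of the regions, 66.2% of which were CpG-rich, so medians near 0 in the larger classes carry no information on a displacement.

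**Figure D2:**
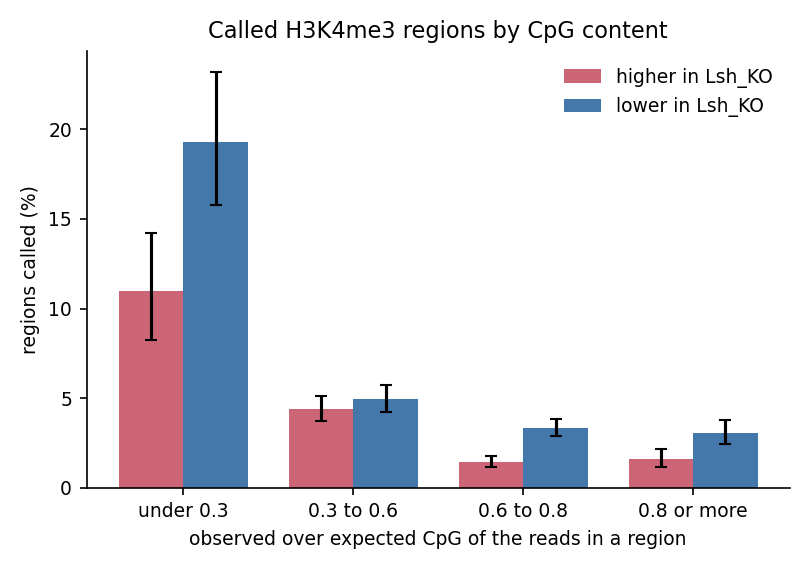
Percent of H3K4me3 regions called higher or lower in Lsh_KO, by the observed over expected CpG of their reads, scaled by the median ratio, with exact 95% intervals of counting error (1 library per line). Scaling by total reads turns the balance of higher and lower calls in CpG-rich and CpG-poor regions. Below 0.3, 10.96% were higher and 19.3% lower, and from 0.8 upward 1.58% and 3.05%.

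Whole chromosomes differed in background reads, outside marked windows. Ratios of background reads were scaled by their total over all chromosomes, not by the median ratio of marked windows. Chromosome 18 had a log2 ratio of Lsh_KO over WT of 0.49 (0.48 to 0.51), and chromosome 16 one of -0.44 (-0.46 to -0.43). All 18 bins of 5 Mb on chromosome 18 lay above 0 and all 20 on chromosome 16 below. Chromosome 6 stood at 0.26, with 30 of 30 bins above 0, and chromosome 4 at -0.25. Marked windows moved with their chromosome: their median log2 ratio was 0.43 on chromosome 18 and -0.28 on chromosome 16. Across 20 chromosomes, which are not replicates, the median of marked windows followed the background with Pearson's r of 0.969 and Spearman's rho of 0.944, and r was 0.943 without chromosomes 16 and 18. Chromosome 18 gave 85 higher and 19 lower windows, and 29 and 40 after the 5 Mb background ratio was taken into the scaling. Chromosome 16 gave 4 and 50, and 16 and 32 after it. Chromosome Y held 11 distinct reads in WT and 15 in Lsh_KO over 1198 windows.

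**Figure D3:**
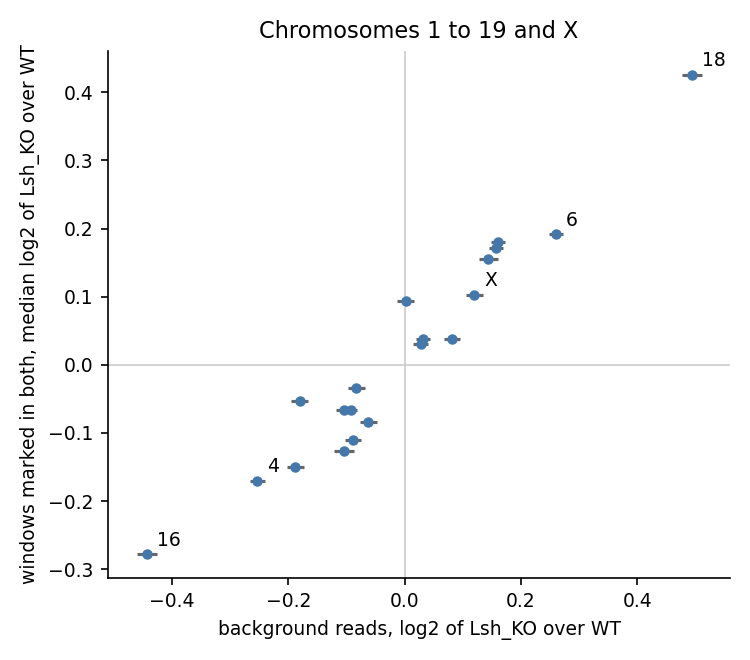
Median log2 ratio of Lsh_KO over WT in windows marked in both libraries against the log2 ratio of background reads, 1 point per chromosome, with exact 95% intervals of the background ratio from counting error. Chromosome 18 lies highest at 0.49 and 0.43 and chromosome 16 lowest at -0.44 and -0.28.

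The fragment length read from the offset of opposite strands was 104 bp in WT and 103 bp in Lsh_KO. The nucleosome repeat was taken where same-strand distances rose farthest above a fitted straight line, at 183 and 188 bp over all chromosomes. The distances themselves had no peak there: they fell from 0.185% of pairs at 148 bp in both libraries to 0.181% at 183 bp in WT and 0.180% at 188 bp in Lsh_KO. The repeat is therefore a weak estimate. Estimated per chromosome, Lsh_KO minus WT averaged 0.70 bp (SD 19.6 bp, 20 chromosomes) for the repeat, above 0 on 9 chromosomes and below on 10. Repeat-like reads made up 0.262% (0.254 to 0.269) of the 1811336 WT reads outside marked windows and 0.245% (0.238 to 0.253) of the 1799030 such Lsh_KO reads. The difference was in the direction of fewer repeat-like reads in Lsh_KO, and only repeats with a uniquely placed read could be counted.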

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

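The tests of lane errors, of GC content, of whole-chromosome copies and of a different height over background (a scaling of regions set by read number) were chosen only after the result was seen.

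Base mismatches in the read sequences, which had no part in calling windows or regions, were denser in some blocks of the Lsh_KO library. Sites where at least 2 distinct Lsh_KO reads carried the same mismatch, and fewer than 2 WT reads did, numbered 87 on chromosome 19 from 35 to 50 Mb, 74 on chromosome 2 from 140 to 175 Mb and 62 on chromosome 5 from 15 to 35 Mb. In WT the same blocks held 3, 4 and 1 such sites. The blocks held 223 of the sites found only in Lsh_KO, the blocks picked for WT 16, and the other 497 bins of 5 Mb 1012, of which 11 shorter stretches with a raised mismatch share held 224 (76 of them on chromosome 7 from 15 to 25 Mb). The blocks were picked out because their mismatch share in Lsh_KO stood above that in WT.

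Random errors of the lane would seldom recur in further reads over a site, but leaving out 2 reads per site, 67.2% of 235 further Lsh_KO reads carried the mismatch base (95% interval 60.8 to 73.2). Reads from near-identical copies elsewhere would carry the same base in WT, where 0.635% of 315 reads over these sites did (0.0770 to 2.27), and none of the 223 sites repeated in Lsh_KO was also repeated in WT. A haplotype in the Lsh_KO line that differs from the reference is a candidate explanation that stays open. The 67.2% lies below the 80% set in advance for a block without the reference base, but this comparison cannot decide the question. Leaving out 2 reads with the mismatch base lowers the share only at sites where other reads lack that base. In a block without the reference base it would lower nothing, so it does not account for the gap to 80%. Sites only in Lsh_KO also occurred in the other bins, at 41.7 per 100000 reads against 209 in the blocks. How many of the 223 block sites were of that kind was not determined, which leaves the question undecided. Hells lies on chromosome 19 in assembly GRCm38.p6, and DNA of another strain kept around a targeted gene may be part of the block on that chromosome, which was not tested.

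The background of whole chromosomes also differed between the lines, most on chromosomes 16 and 18. A GC bias between the libraries would vanish within strata of read GC content, where chromosome 18 kept a log2 ratio of 0.49. Spill-over from marked windows would vanish far from them, and over 50 kb from any marked window chromosome 18 still stood at 0.47 (95% interval 0.45 to 0.49). A different number of copies of these chromosomes in part or all of the cells of the 2 lines may explain it and stays open: it predicts an equal shift of marked windows, whose median log2 ratio was 0.43 on chromosome 18 (0.38 to 0.49, background 0.49) and -0.28 on chromosome 16 (-0.31 to -0.22, background -0.44), in the same direction but smaller. Whether such a difference arose from loss of Lsh or in culture was not tested.

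CpG-poor regions were called more often than CpG-rich ones in both directions. Counting error at low read numbers was tested in regions of 40 to 120 reads, where CpG-poor regions were still called 2.04 times as often (11.9% against 5.83%). With the 5 Mb background ratio in the scaling the factor was 2.71, and with a scaling set by read number it was 2.70, which argues against copy number and against a different height over background as the whole cause. Regions drawn in only 1 library entered partly because of a difference between the libraries. Of the 3994 CpG-poor regions, 252 were drawn only in WT and 499 only in Lsh_KO, against 188 and 329 of the 7826 CpG-rich ones. The tests above did not address this selection. Differences between any 2 fibroblast lines and an effect of Lsh loss on CpG-poor sequence both stay open as hypotheses, since each genotype had 1 library.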

How the results depend on the processing

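No paired analysis was possible because each group had 1 library. The scalings with the 5 Mb background ratio, GC content or read number, the deposited window list, windows starting 1 kb later and an alignment score above 20 were chosen after seeing the data. Scaling by total reads or TMM shifts every locus by 1 constant (0.33 and 0.19 on the log2 scale), so it hardly tests loci this far from the threshold. All 30 stayed past the calling rule in their direction with all reads, the 5 Mb background ratio, the deposited window list and 4 kb windows, which moved 3, 1, 10 and 14 of them by over 1.5 times. In 1 kb windows, where the value is that of the 1 window with the farthest bound, 19 moved by over 1.5 times (up to 7.57 times) and 28 stayed past the rule, while those starting at 8904001 on chromosome 19 and 33000001 on chromosome 2 kept only their direction. Higher and lower windows stayed within 1.5 times of 730 and 1228 with windows of 1 kb (927 and 935), reads not moved, thinning, background subtraction, the 5 Mb background ratio (612 and 1253), GC content, read number (815 and 1080), windows starting 1 kb later and scores above 20. Of the main calls, 658 higher and 1036 lower windows were shared with read number, 516 and 1065 with the 5 Mb background ratio, and 597 and 1022 with the deposited window list.

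Scaling turned the balance of directions: higher windows made up 71.6% of calls with total reads, 56.9% with TMM (1215 higher, 922 lower) and 84.1% with background reads (2966 and 562), each factor being smaller than the median ratio. Total reads gave 1837 and 730 windows, and 887 and 290 regions. The balance also turned at a minimum of 50 reads (53.5% higher, 275 and 239). All reads with repeats gave 1114 and 2033 windows, windows of 4 kb 2649 lower, no minimum of reads 2130 and 14056, the deposited window list 1566 and 3490, at least 1.5-fold 1339 higher, and at least 3-fold 313 and 683. The cause was not tested, except that stricter or looser rules count fewer or more windows by construction. Gained and lost windows were 203 and 120 at 10 times background and 4739 and 4960 in the deposited window list. Thinning gave 595 gained and all reads 1136 lost. Marking at 3 times background moved nothing, as the minimum of 10 reads was the stricter rule. Regions at or above the median read number, compared only with such regions of the other library, overlapped in 87.9% of WT and 85.1% of Lsh_KO cases. With marked windows included, the ratios of chromosomes 16 and 18 were -0.42 and 0.46, outside their counting intervals, and with all reads -0.45 and 0.48, inside them. Repeat-like shares stayed within their counting intervals. Alternatives that need start sites or gene types (outermost 5' ends, protein-coding genes, distance classes, profile scaling, gene lists) were not run. Among windows marked in both libraries, 57.0% of simulated 2-fold higher and 42.0% of 2-fold lower windows were recovered. A 2-fold change lies at the calling threshold itself, so these shares say little about depth. At 3-fold, 98.5% and 76.5% were recovered.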

Other observations

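The lower clusters repeated in the further reads of the deposited window lists. The chromosome 11 cluster from 96086001 to 96138000 held 350 WT and 29 Lsh_KO further reads, 17.3-fold lower in Lsh_KO, and the chromosome 8 cluster from 60204001 to 60228000 held 601 and 84, 10.2-fold lower. These values again cover the called windows alone. The single higher locus of 5 windows was on chromosome 13, from 120606001 to 120616000, with 32 and 162 reads, 3.56-fold higher, and 23.7% of its reads carried a mismatch.

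WT also had blocks of mismatches. On chromosome 15 from 30 to 45 Mb, 19 repeated sites were found only in WT and 3 only in Lsh_KO. On chromosome 12 from 15 to 35 Mb the share of mismatched reads was 15.3% in WT and 9.80% in Lsh_KO, but repeated sites were nearly equal, 14 and 13. Shorter stretches with a raised mismatch share in WT numbered 13 and held 117 sites only in WT and 18 only in Lsh_KO. The farthest apart were chromosome 8 from 90 to 100 Mb (13.6% in WT and 7.60% in Lsh_KO, 28 sites only in WT and 0 only in Lsh_KO) and chromosome 1 from 170 to 175 Mb (11 sites only in WT and 1 only in Lsh_KO). Windows in all mismatch blocks were called in 9.51% of cases, against 9.24% elsewhere. On the X chromosome, 22 of 351 regions were higher and 13 lower, and its background ratio was 0.12 on the log2 scale, 0.07 within strata of GC content, 0.05 over all distinct reads and 0.01 over all reads. Among windows with at least 50 reads, the 426 where over 25% of reads carried a mismatch were higher in 3.05% and lower in 2.58% of cases, against 2.10% and 1.83% of the other 12451.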
